A study of Mus musculus with 2 samples.

How the data were processed

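Total RNA was measured by sequencing in common myeloid progenitors, blood-forming progenitors that give rise to granulocytes, monocytes, megakaryocytes and red cells. The cells came from male adult C57BL/6J mice aged 5 to 6 weeks, per the labels. There were 2 libraries of 1 group, called biological replicates 1 and 2 in the labels. Both carry the same donor label, so the spread between them measures the spread of these 2 samples and may be partly technical. Libraries were made with a ScriptSeq kit from 100 ng of RNA depleted of ribosomal RNA, per the labels. The stated size ranges were 200 to 1000 for replicate 1 and 187 to 1606 for replicate 2, with no unit given.

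The authors deposited a gene table and a transcript table per library on mm10 with GENCODE M4, per the readme of each library. The aligner and the quantifier were not given in the sources used here. Expected counts, per the file headers, are estimated reads per gene or transcript that need not be whole. TPM and posterior mean TPM, per the file headers, are corrected for effective length and are relative to all entries of the deposited table, short structural RNAs included. FPKM values were deposited in the same tables. FPKM and posterior mean TPM served as alternatives. The deposited percent of each gene's abundance per transcript was not used, because shares were computed from transcript TPM. Deposited interval bounds of TPM were not used here. Each gene table held 69691 entries, of which 43346 were Ensembl genes, 26248 had a numeric identifier and 97 were spike-in sequences. Spike-in sequences had 0 counts in both libraries. Entries with a numeric identifier had 0 counts in replicate 1 and 83 in replicate 2. These entries stayed out of library sizes.

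Total expected counts were 28158803 in replicate 1 and 84041137 in replicate 2. A count of 0 allows up to 3 counts, which is 0.107 CPM (expected counts scaled to the library total) in replicate 1 and 0.0357 CPM in replicate 2. Reads without molecular identifiers are not independent molecules, so such limits cover counting error only. Gene names, classes and coordinates came from GENCODE M21 on GRCm38, the same assembly as mm10, matched by Ensembl gene ID. Of the gene entries, 42462 matched, and the unmatched entries held 0.277% of counts in each library.

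With 1 group there was no comparison between conditions and no p-value. Before the data were examined, 25 gene lists, the results, the alternatives and a rule for named genes were fixed. By that rule every member of the surface protein, receptor, transcription factor, chromatin and kinase inhibitor lists could be named, with the 5 highest and 3 lowest members of other lists by mean TPM. The 20 genes of highest mean TPM and the 5 genes of largest ratio each way between libraries, at a mean expected count of at least 50, could also be named. Symbols of 272 of 274 list genes were matched; Ahsp and Snhg1 were not analysed here. A list's level was the median TPM of its members in each library.

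Library sizes were scaled with TMM in edgeR 4.0.16, with size factors of DESeq2 1.42.0 as the alternative, on expected counts rounded to whole numbers in R 4.3.3. The coefficient of variation was the square root of edgeR's common dispersion over genes with at least 1 CPM in both libraries. Log2 CPM ratios were taken as replicate 2 over replicate 1 with a prior count of 0.5. Counts of genes that differed at least 2-fold were set beside 100 Poisson simulations. List ratios used members with a mean expected count of at least 10 and lists with at least 3 such members, against 10000 random lists of the same size matched on mean expression in 20 bins. Dominant transcripts were read for genes with at least 100 expected counts in each library. Only the surface protein, receptor, transcription factor and chromatin lists were used for this. The GC content of a gene was that of its longest M21 transcript. Intervals over genes are the central 95% of 1000 bootstrap samples of genes, which are not independent replicates. For shares of snoRNA and other short RNA they come from counting error widened by the ratio of observed to Poisson variance. That ratio was larger for genes with many reads, so intervals of shares held by such genes may be too narrow. Of the RNA classes, 7SK and 7SL RNA were separated from other classes after seeing the data. The remaining steps ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

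The steps were tested on simulated data with the real genes, means and depths, over 43346 genes. With 200 genes changed 8-fold, 100% were recovered at 2-fold or more, and 2.42% of unchanged genes passed it. A simulated coefficient of variation of 0.2 came out as 0.1997 over unchanged genes, and as 0.258 with the changed genes included. Of 200 random lists of 12 unchanged genes, 6.5% fell outside the central 95% of matched lists. These simulations gave every gene the same relative spread, unlike the data. Their ratio of observed to Poisson variance was 3.78 at 80 to 160 reads and 53.2 at 1280 to 2560 reads, against 26.4 and 30.2 in the data. The rates above therefore do not carry over to the real libraries, least of all at low counts. Alternatives covered the unit, the pseudocount, filters on low values, the scaling and each library alone. Others were added after seeing the data, among them TPM rescaled to nuclear protein-coding genes.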

Results

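Total RNA was sequenced from common myeloid progenitors of male mice in 2 libraries of 1 group. Replicate 1 held 28158803 expected counts and replicate 2 held 84041137, 2.98 times as many. Pairs of counts given below are not scaled for this difference in depth. Levels are mean TPM ± SD over both libraries (n = 2), and coordinates are those of GENCODE M21 on GRCm38. TPM of at least 1 in both libraries was reached by 9981 genes, of which 9116 were nuclear protein-coding genes, and TPM of at least 5 by 5737.

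Which progenitor surface proteins and receptors the cells transcribed was addressed first. Cd34, the sialomucin of early blood progenitors, stood at 123 ± 2.84 TPM and Kit, the stem cell factor receptor, at 36.6 ± 4.47 TPM. Itga2b, an integrin chain of megakaryocytes and early progenitors, stood at 30.9 ± 1.03 TPM, Cd48 at 27.6 ± 6.22 TPM and the receptor gene Flt3 at 22.9 ± 2.8 TPM. Ly6a, which encodes the stem cell antigen Sca-1, was far lower at 0.71 ± 0.0283 TPM. Of the surface protein list, 9 of 12 members reached 1 TPM in both libraries, with a list median of 9.5 ± 0.576 TPM. The Fc receptor genes Fcgr2b and Fcgr3 stood at 6.2 ± 0.12 TPM and 2.56 ± 1.31 TPM. Their counts in replicate 2, 1591.39 and 748.61, were not whole, so reads were divided between models and both levels are uncertain. A retained intron model held 72.6% of Fcgr3 TPM in replicate 2 and 0% in replicate 1. Cd9 and Eng stood at 12.8 ± 1.03 TPM and 4.52 ± 1.13 TPM. Slamf1 stood at 0.945 ± 0.12 TPM. Il7r, the interleukin-7 receptor of lymphoid progenitors, had 218 and 76 counts in replicates 1 and 2. Scaled for depth these were 7.74 and 0.904 CPM, so Il7r was lower in replicate 2. In the annotation, Cd34 (ENSMUSG00000016494.5), chromosome 1 from 194938819 to 194961279, and Kit (ENSMUSG00000005672.8), chromosome 5 from 75574916 to 75656722, are protein-coding genes.

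Cytokine receptor genes were lower, with a median of 2.71 ± 0.541 TPM and 10 of 12 members at 1 TPM in both libraries. Ifngr1, an interferon gamma receptor chain, was the highest at 26.5 ± 2.33 TPM. Csf3r and Csf1r, the receptors of granulocyte and macrophage colony-stimulating factors, stood at 7.25 ± 0.41 TPM and 5.12 ± 0.29 TPM. Epor, the receptor of erythropoietin, stood at 3.38 ± 1.48 TPM. Il6st, Il6ra and Il3ra stood at 6.83 ± 1.36 TPM, 2.62 ± 0.445 TPM and 2.52 ± 0.106 TPM. Csf2ra stood at 1.93 ± 0.0849 TPM and Csf2rb at 2.44 ± 1.12 TPM, while Csf2rb2 stood at 0.265 ± 0.00707 TPM; the last pair are close copies, so the split of reads between them is uncertain. Il5ra had 0 and 87 counts in replicates 1 and 2.

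Transcription factor genes of both myeloid branches were detected in each library. RNA of many cells was pooled, so whether the same cells or a mix of cells transcribed them cannot be told. The progenitor factors had a median of 21.1 ± 2.19 TPM, and 12 of 12 reached 1 TPM in both libraries. Myb was the highest at 95.1 ± 15.5 TPM, followed by Lmo2 at 82.6 ± 4.69 TPM and Ikzf1 at 44.2 ± 4.34 TPM. Erg, Etv6, Meis1 and Myc lay between 20.9 ± 4.41 TPM and 26.6 ± 0.332 TPM. Runx1 stood at 18.6 ± 2.88 TPM, Gata2 at 11.3 ± 3.39 TPM, Hoxa9 at 10.99 ± 1.01 TPM, Lyl1 at 9.35 ± 1.8 TPM and Tal1 at 9.3 ± 1.82 TPM. Myb (ENSMUSG00000019982.10), chromosome 10 from 21124935 to 21160984, is the gene of a factor needed for definitive blood formation.

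By list medians, megakaryocyte-erythroid factors stood above granulocyte-monocyte factors in both libraries. The former had a median of 13.6 ± 2.33 TPM and the latter 2.29 ± 0.601 TPM. On the log2(TPM + 1) scale the difference of medians, granulocyte-monocyte minus megakaryocyte-erythroid, was -2.17 in replicate 1 and -2.15 in replicate 2, a mean of -2.16 ± 0.01 (SD, n = 2). The difference was not tested. It is that of the lists as fixed beforehand, and other choices of factors were not tried. Lists of lineage products followed no single order. Their medians were 38.04 TPM for primary granule, 8.05 TPM for monocyte and macrophage and 5.3 TPM for late neutrophil genes. Those of erythroid and of megakaryocyte and platelet genes were 8.59 and 1.87 TPM. Gata1, the erythroid and megakaryocyte regulator, stood at 10.6 ± 1.19 TPM, Klf1 at 16.2 ± 0.594 TPM, Nfe2 at 27.6 ± 3.27 TPM, Ldb1 at 32.4 ± 5.4 TPM and Fli1 at 19.3 ± 0.396 TPM. Bcl11a, Zfpm1, Gfi1b and Mafg stood at 17.1 ± 4.72 TPM, 12.5 ± 3.27 TPM, 6.49 ± 0.46 TPM and 4.54 ± 0.0707 TPM, and Sox6 at 0.935 ± 0.0495 TPM.

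Among granulocyte-monocyte factors, 6 of 10 reached 1 TPM in both libraries. Irf8, a regulator of monocyte and dendritic cell fates, was the highest at 23.2 ± 3.95 TPM, with Spi1, the gene of PU.1, at 14.96 ± 2.16 TPM. Both stood above Gata1 in each library, at 20.43 and 26.02 TPM for Irf8 and 13.44 and 16.49 TPM for Spi1 against 9.73 and 11.41 TPM for Gata1. Cebpa, needed for granulocyte formation, stood at 3.36 ± 1.07 TPM, below Gata1 in both libraries. Cebpd, Egr2, Gfi1 and Cebpb stood at 3.65 ± 0.672 TPM, 2.49 ± 1.16 TPM, 2.09 ± 0.0424 TPM and 1.21 ± 0.325 TPM. Klf4, Rara and Cebpe, a factor of late granulocytes, stood at 0.44 and 1.22 TPM, 0.26 and 1.23 TPM and 0.24 and 1.1 TPM in replicates 1 and 2. With TPM rescaled to nuclear protein-coding genes they stood at 2.19 and 5.67, 1.29 and 5.71 and 1.19 and 5.11, above 1 in both libraries. In the annotation, Gata1 (ENSMUSG00000031162.10), chromosome X from 7959260 to 7978071, and Cebpa (ENSMUSG00000034957.9), chromosome 7 from 35119293 to 35121928, are protein-coding.

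**Figure D1:**
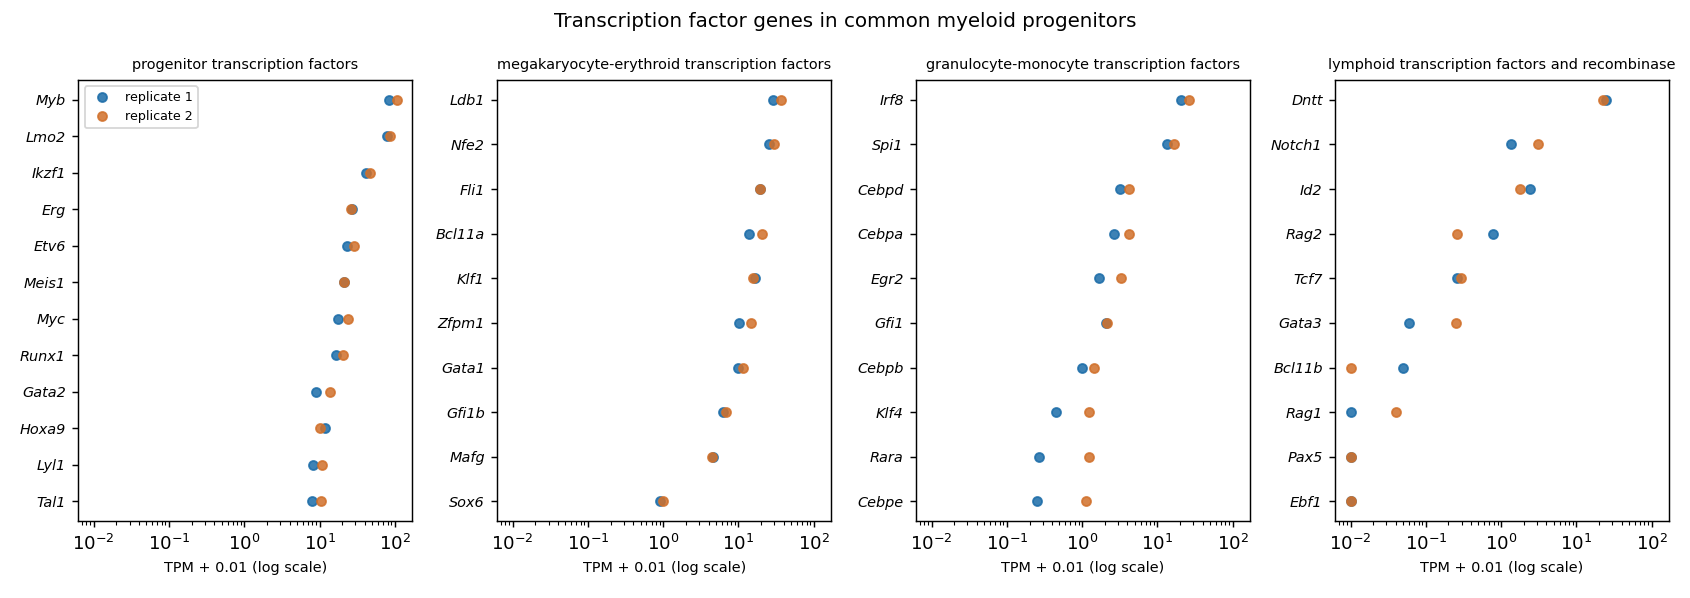
TPM + 0.01 on a log axis for each member of the transcription factor lists, with 1 point per library. Myb at 95.1 ± 15.5 TPM was the highest of these genes, and Pax5 and Ebf1 had 0 counts in both libraries.

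Of the lymphoid factors and recombinase genes, 3 of 10 reached 1 TPM in both libraries, for a median of 0.198 ± 0.0672 TPM; it was 0.505 ± 0.297 TPM with posterior mean TPM and 1.04 ± 0.0247 TPM over members with at least 10 counts in both libraries. Dntt, the template-free polymerase of early lymphoid cells, stood well above the rest at 23.7 ± 1.62 TPM. Notch1 and Id2 stood at 2.19 ± 1.21 TPM and 2.1 ± 0.481 TPM, and Notch1 at 4.17 ± 0.262 TPM with posterior mean TPM. The recombinase genes Rag1 and Rag2 were low, with 0 and 43 counts for Rag1 in replicates 1 and 2 and 189 and 156 for Rag2. Tcf7 had 33 and 122 counts, Gata3 had 12 and 143 and Bcl11b had 25 and 0. Ebf1 and Pax5, factors of B cell commitment, had 0 counts in both libraries. By counting error alone, this allows up to 0.107 CPM in replicate 1 and 0.0357 CPM in replicate 2.

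The primary granule list stood above the late neutrophil list in both libraries, by list medians. The primary granule list had a median of 38.04 ± 2.95 TPM, and 8 of 8 members reached 1 TPM in both libraries. Not all of its members encode proteins stored in granules, so the median is that of the list as fixed beforehand. Of the list, Plac8 and Mpo, the gene of myeloperoxidase, were the highest at 417 ± 83.4 TPM and 357 ± 60.1 TPM. Ctsg, Serpinb1a and Prtn3 stood at 105 ± 15.9 TPM, 44.7 ± 0.177 TPM and 31.4 ± 5.73 TPM, and Elane, neutrophil elastase, at 17.8 ± 4.44 TPM. Late neutrophil genes had a median of 5.3 ± 0.0106 TPM, with S100a8 and S100a9 at 139 ± 3.59 TPM and 69.5 ± 2.31 TPM and Ngp, Camp and Ltf at 28.1 ± 3.85 TPM, 14.4 ± 0.247 TPM and 7.36 ± 0.827 TPM. The matrix metalloproteinase genes Mmp8 and Mmp9 stood at 0.795 ± 0.00707 TPM and 0.225 ± 0.00707 TPM, and Ly6g had 23 and 0 counts in replicates 1 and 2. Mpo (ENSMUSG00000009350.9), chromosome 11 from 87793581 to 87804413, is protein-coding.

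Monocyte and macrophage genes had a median of 8.05 ± 0.891 TPM, and 9 of 12 reached 1 TPM in both libraries. Lyz2, lysozyme, stood at 57.5 ± 1.34 TPM, Ly86 at 26.9 ± 2.22 TPM, Ms4a6c at 23.7 ± 0.318 TPM, F13a1 at 23.4 ± 1.79 TPM and Ly6c2 at 14.5 ± 3.43 TPM. The macrophage genes Adgre1 and C1qa stood at 0.395 ± 0.205 TPM and 0.44 ± 0.17 TPM. Dendritic cell and antigen presentation genes had a median of 1.09 ± 0.141 TPM, or 2.84 ± 0.944 TPM over members with at least 10 counts in both libraries, with H2-Ab1 at 17 ± 2.97 TPM, Bst2 at 9.66 ± 2.69 TPM and Tcf4 at 9.37 ± 1.82 TPM. Siglech, a plasmacytoid dendritic cell gene, had 2 and 3 counts and Xcr1 had 0 counts in both libraries.

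Erythroid genes were led by carbonic anhydrases rather than by globins. Car1 and Car2 stood at 174 ± 12.1 TPM and 129.9 ± 2.76 TPM, and Tfrc, the transferrin receptor, at 28.9 ± 1.8 TPM. The globin genes Hba-a2 and Hbb-bs stood at 19.6 ± 1.4 TPM and 2.31 ± 0.325 TPM; globin copies are near-identical, so each one's level is uncertain. Ermap stood at 17.8 ± 3.29 TPM. Slc4a1 and Alas2, genes of maturing red cells, stood at 0.39 ± 0.311 TPM and 0.145 ± 0.0778 TPM, and Slc4a1 at 0.825 ± 0.544 TPM with posterior mean TPM. The list median was 8.59 ± 0.785 TPM, with 11 of 13 at 1 TPM in both libraries. Car1 (ENSMUSG00000027556.11), chromosome 3 from 14766216 to 14808368, is protein-coding.

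Megakaryocyte and platelet genes had a median of 1.87 ± 0.226 TPM, and 8 of 12 reached 1 TPM in both libraries. Besides Itga2b, Pf4, the gene of platelet factor 4, stood at 26.8 ± 5.2 TPM. Vwf, Treml1 and Gp9 stood at 3.44 ± 0 TPM, 2.86 ± 0.495 TPM and 2.69 ± 0.884 TPM, and Ppbp at 0.24 ± 0.0849 TPM. Gp1ba had 21 and 342 counts in replicates 1 and 2. In the mast cell, basophil and eosinophil list, 5 of 12 members reached 1 TPM in both libraries, for a median of 0.588 ± 0.364 TPM (0.33 and 0.845 TPM in replicates 1 and 2), or 4.03 ± 0.555 TPM over members with at least 10 counts in both. Cpa3, mast cell carboxypeptidase, stood at 31.3 ± 0.834 TPM, Ms4a2 at 12.3 ± 1.33 TPM, Prg2 at 6.73 ± 1.29 TPM, Mcpt8 at 4.18 ± 0.955 TPM and Hdc at 3.88 ± 0.156 TPM. The mature mast cell protease genes Cma1 and Tpsb2 and the eosinophil receptor gene Ccr3 had 0 counts in both libraries.

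Stem cell genes had a median of 1.1 ± 0.375 TPM, and 5 of 12 reached 1 TPM in both libraries. Mllt3, Hlf, Pdzk1ip1, Tek and Ctnnal1 stood at 6.68 ± 0.148 TPM, 2.73 ± 1.15 TPM, 2.39 ± 0.467 TPM, 2.21 ± 0.29 TPM and 2.1 ± 0.559 TPM. Procr, the endothelial protein C receptor, had 9 and 150 counts in replicates 1 and 2, Fgd5 had 92 and 136, and Hoxb5 had 0 in both. Scaled for depth, Procr stood at 0.32 and 1.78 CPM and Fgd5 at 3.27 and 1.62 CPM, so that Fgd5 was lower in replicate 2.

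Markers of B cells, T and NK cells and stromal cells had the lowest list medians. The B cell list had a median of 0 TPM in both libraries, and 6 of 10 members had 0 counts in both, among them Pax5. Ighm, the immunoglobulin mu constant region, was the highest at 33.8 ± 1.3 TPM, with Cd79b at 3.9 ± 0.318 TPM. T and NK cell genes had a median of 0.105 ± 0.0849 TPM (0.045 and 0.165 TPM in replicates 1 and 2), with Nkg7 at 18.8 ± 0.948 TPM, Lck at 2.79 ± 1.55 TPM and Cd3e, Cd8a and Ncr1 at 0 counts. Stromal and endothelial genes had a median of 0.0025 ± 0.00354 TPM (0 and 0.005 TPM in replicates 1 and 2), and 1 of 12 members reached 1 TPM in both libraries, Pdgfrb at 3.88 ± 0.841 TPM. With posterior mean TPM the B cell, T and NK cell and stromal medians were 0.05 ± 0.00707 TPM, 0.182 ± 0.0389 TPM and 0.1 ± 0.0566 TPM, and over members with at least 10 counts in both libraries 3.9 ± 0.318 TPM, 0.275 ± 0.148 TPM and 0.37 ± 0.269 TPM. Ighm (ENSMUSG00000076617.5), chromosome 12 from 113418558 to 113422730, is an immunoglobulin constant gene, and Pdgfrb (ENSMUSG00000024620.7), chromosome 18 from 61045150 to 61085061, is protein-coding.

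**Figure D2:**
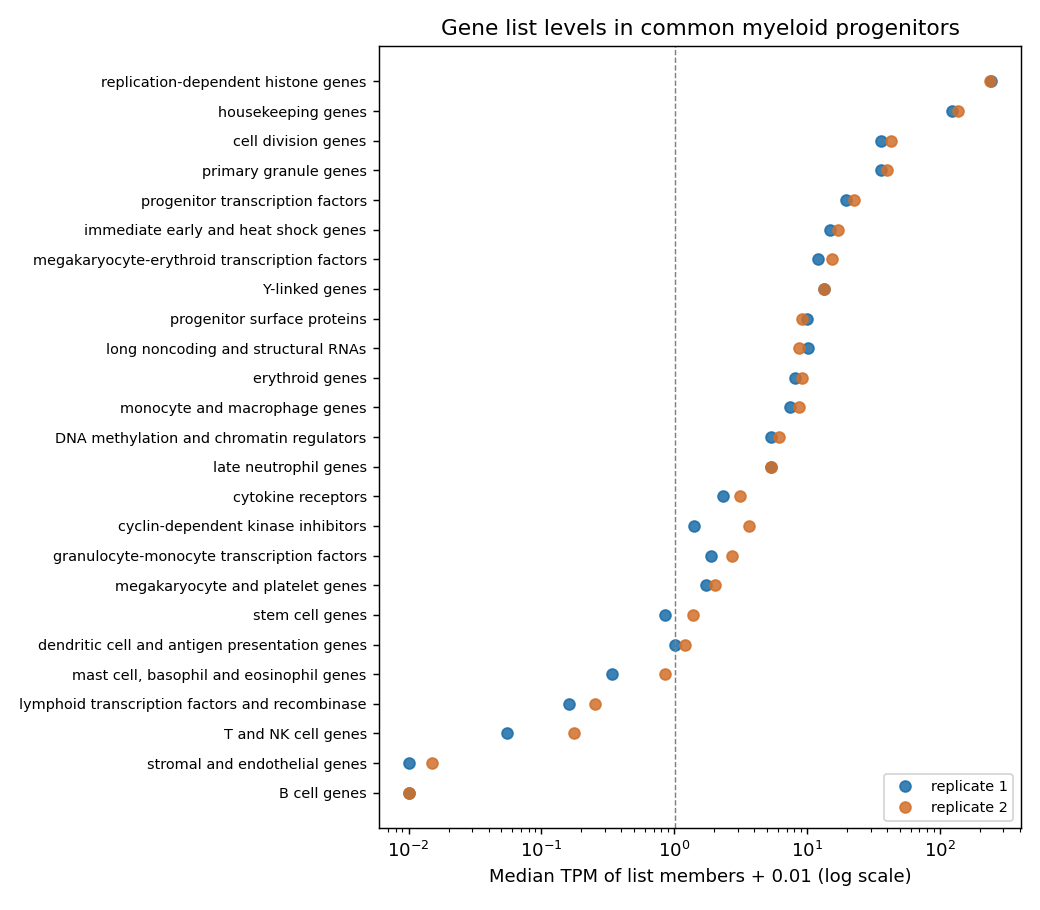
Median TPM + 0.01 of the members of each gene list on a log axis, with 1 point per library and a dashed line at 1 TPM. The replication-dependent histone list was the highest at 240.2 ± 4.32 TPM, and the B cell list was at 0 TPM in both libraries.

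Cell division genes were high, with a median of 39.5 ± 4.89 TPM and 12 of 12 at 1 TPM in both libraries. Top2a, topoisomerase II alpha, and Pcna, the replication clamp, stood at 137 ± 10.2 TPM and 137 ± 9.28 TPM, Mki67 at 90.01 ± 10.7 TPM, Cdk1 at 48.3 ± 0.559 TPM and Ccna2 at 46.1 ± 2.2 TPM. Replication-dependent histone genes, transcribed in S phase, had a median of 240.2 ± 4.32 TPM, and Hist1h4d stood at 1709.9 ± 106 TPM. Histone genes share reads with near-identical copies, so single members are uncertain. Of the cyclin-dependent kinase inhibitors, Cdkn1b was the highest at 13.5 ± 0.41 TPM, then Cdkn2c at 7.6 ± 0.0849 TPM, Cdkn3 at 4.83 ± 0.926 TPM and Cdkn2d at 3.97 ± 2.77 TPM. Cdkn1a and Cdkn1c stood at 1.25 ± 0.686 TPM and 0.135 ± 0.0354 TPM, Cdkn2a and Cdkn2b had 0 counts in both libraries, and the list median was 2.5 ± 1.57 TPM (1.39 and 3.61 TPM in replicates 1 and 2), or 4.4 ± 1.85 TPM over members with at least 10 counts in both.

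DNA methylation and chromatin regulators had a median of 5.71 ± 0.552 TPM, and 14 of 14 reached 1 TPM in both libraries. Ezh2, the Polycomb methyltransferase, stood at 62.2 ± 2.45 TPM against 4.12 ± 1.01 TPM for its relative Ezh1. The gap was smaller without length correction, at 184 and 187 CPM for Ezh2 and 40.9 and 27.8 CPM for Ezh1 in replicates 1 and 2. Dnmt1, the maintenance methyltransferase, stood at 52.9 ± 6.5 TPM, and the de novo enzymes Dnmt3a and Dnmt3b at 5.24 ± 0.481 TPM and 6.29 ± 0.481 TPM. Tet1, Tet2 and Tet3 stood at 3.43 ± 1.17 TPM, 4.63 ± 0.467 TPM and 4.26 ± 1.22 TPM, and Idh2 and Idh1 at 50.99 ± 3.42 TPM and 13.04 ± 1.06 TPM. Bmi1, Asxl1 and Kmt2a stood at 11.5 ± 0.354 TPM, 7.57 ± 2.57 TPM and 4.42 ± 0.0212 TPM. Dot1l stood at 1.59 and 4.35 TPM in replicates 1 and 2.

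Housekeeping genes had a median of 129 ± 9.05 TPM, from Eef1a1 at 3256 ± 211 TPM to Tbp at 11.5 ± 2.09 TPM. Immediate early and heat shock genes had a median of 15.99 ± 1.51 TPM, with Fos and Jun at 98.6 ± 15.3 TPM and 72.7 ± 16.7 TPM and Nr4a1 at 4.4 ± 0.806 TPM. The Y-linked genes had a median of 13.4 ± 0.0212 TPM, and 4 of 4 reached 1 TPM in both libraries of these male mice. Xist, the X inactivation RNA, had 0 and 26 counts in replicates 1 and 2. The long noncoding and structural RNA list had a median of 9.46 ± 1.07 TPM, but 677 ± 55.6 TPM over members with at least 10 counts in both libraries, with Malat1 at 677 ± 55.6 TPM and Gas5 at 468 ± 25.9 TPM. Meg3 had 0 counts in both libraries.

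Small structural RNAs held most of the TPM and a far smaller share of the reads. Rn7sk, the 7SK RNA that restrains transcription elongation, held 22.8% ± 3.19 of TPM (SD, n = 2), and small nuclear RNAs, parts of the spliceosome, held 23.5% ± 3.26. Small nucleolar and Cajal body RNAs held 24.6% of TPM in replicate 1 and 12.5% in replicate 2. Nuclear protein-coding genes held 20.8% ± 1.01 of TPM but 80.99% ± 1.15 of expected counts. Ribosomal protein genes held 4.54% ± 0.127 of TPM, replication histones 1.57% ± 0.166 and mitochondrial protein-coding genes 1.24% ± 0.0585. Gene models under 200 nt held 41.8% ± 5.31 of TPM and 1.14% ± 0.0905 of expected counts. The 20 genes of highest mean TPM were all structural RNAs shorter than 350 nt, 12 of them snRNA genes; U1 and U2 copies among them share reads and are uncertain one by one. After Rn7sk came Gm22422, a snoRNA gene of 135 nt with modelled effective lengths of 3.73 and 5.08 nt in replicates 1 and 2, so that its TPM is uncertain. It lies on chromosome 16 from 56035753 to 56035887. Rpph1, the RNase P RNA, stood at 33218 ± 988 TPM. Rescaling TPM to nuclear protein-coding genes alone was an alternative added after seeing the data and multiplies each value by 4.98 in replicate 1 and 4.65 in replicate 2. The counts of list members at 1 TPM given above are those before rescaling, and more members of some lists pass on the rescaled values.

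**Figure D3:**
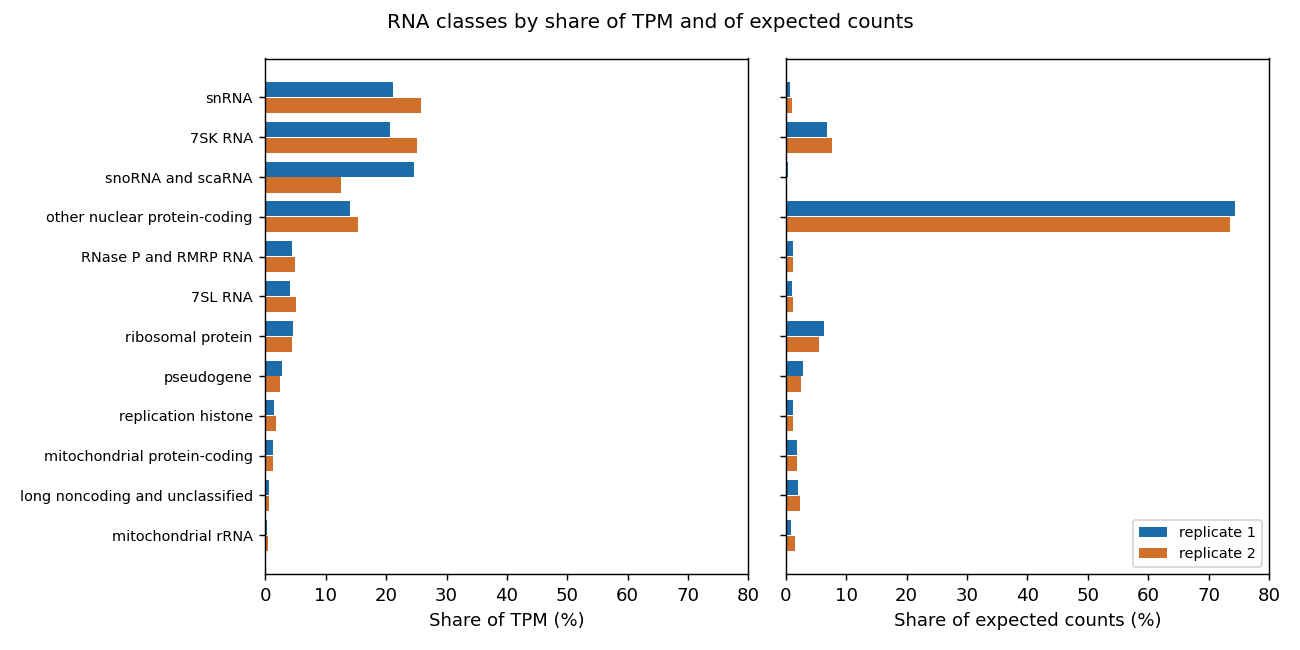
Share of TPM (left) and of expected counts (right), in percent, of each RNA class with at least 0.5% of either, with 1 bar per library. Nuclear protein-coding genes held 20.8% ± 1.01 of TPM and 80.99% ± 1.15 of expected counts.

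Dominant transcripts were compared for 66 genes of the surface protein, receptor, transcription factor and chromatin lists. The same transcript was dominant in both libraries for 56 of these 66 genes, and for 45 of the 55 with more than 1 annotated transcript. Flt3-201 held 97.7% ± 0.7999 of Flt3 TPM (SD, n = 2), Irf8-201 97.6% ± 2.05 of Irf8, Tal1-201 95.2% ± 0.963 of Tal1 and Gata1-201 97.9% ± 2.92 of Gata1. Myb-201 held 62.5% ± 0.115 of Myb. For Ezh2 the leading model, Ezh2-209, is annotated as a target of nonsense-mediated decay and held 33.7% ± 0.0544. For Hoxa9 it was the noncoding Hoxa9-203 at 50.6% ± 12.1. The dominant transcript differed for Kit, where Kit-204 held 48.97% in replicate 1 and Kit-201 held 67.7% in replicate 2. It also differed for others, among them Spi1, Fcgr3, Zfpm1, Itga2b, Etv6, Il6st, Sox6 and Tet1. Transcript shares are estimates that divide reads between overlapping models.

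How far the libraries differed was measured across genes. For the genes with at least 1 TPM in either library, Pearson r of log2(TPM + 1) was 0.939 and Spearman rho 0.927 over 11233 genes, which are not independent replicates. The coefficient of variation was 0.215 over 11803 genes, 0.59 with no filter on low values and 0.121 over the 5103 genes with at least 1000 counts in both libraries, a limit added after seeing the data. Of 12704 genes with a mean expected count of at least 50, 1320 differed at least 2-fold, 847 higher in replicate 2 and 473 higher in replicate 1. The count was 3136 at a mean count of at least 10, 411 at 200, 50 at 1000 and 854 over protein-coding genes, the last 2 added after seeing the data. At a mean count of at least 50, Poisson sampling alone gave a mean of 1.23 such genes.

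The largest ratios belonged to genes whose counts were not whole, so reads were divided between models. Gm14440 was at least 708-fold higher in replicate 1 and Gm24924, an snRNA gene, at least 402-fold higher in replicate 2, each against a floor of 3 counts per library. The U3 snoRNA copies went both ways. Rnu3b2 and Rnu3b4 were at least 342-fold higher in replicate 1, while Rnu3b1 and Rnu3b3 were at least 107-fold higher in replicate 2. Gm28035 and Gm12671 were at least 344-fold and 261-fold higher in replicate 1, and Gm28635 and Gm10359 at least 144-fold and 114-fold higher in replicate 2. All 10 are uncertain, and the bounds cover counting error only.

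Of the 25 gene lists, 1 lay outside the central 95% of matched random lists, where chance gives 1.25. It was the histone list, with a median log2 ratio of -0.16 at percentile 0.73. Matching was on mean expression and not on length, and protein-coding genes of 500 to 1000 nt had a median of -0.14. The whole class of 64 replication histone models held 1.14% of expected counts in replicate 1 and 1.16% in replicate 2. Its share was thus not lower in replicate 2. Granulocyte-monocyte factors had a median of 0.40 at percentile 96.7, immediate early genes 0.15 at percentile 97.1 and progenitor factors 0.13 at percentile 97.2. Erythroid genes had a median of -0.14 at percentile 9.19. With the median ratio of 20 GC bins removed, an alternative added after seeing the data, these were -0.25 at percentile 0.05 for histones, 0.27 at 92.6 for granulocyte-monocyte factors, 0.07 at 91.01 for immediate early genes and 0.07 at 92.8 for progenitor factors, the last at 0.08 with TPM ratios. These percentiles describe these libraries and test no condition.

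The ratio varied with transcript length. Genes of 500 to 1000 nt had a median log2 ratio of -0.12 over 1218 genes, genes of 1000 to 2000 nt -0.03, genes of 2000 to 4000 nt 0.02 and genes of at least 4000 nt 0.09 over 2516 genes. Genes under 500 nt, many of them structural RNAs, had 0.08, against -0.10 for the protein-coding ones alone. The range of bin medians was 0.21, and in each bin the quartiles lay on both sides of 0.

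**Figure D4:**
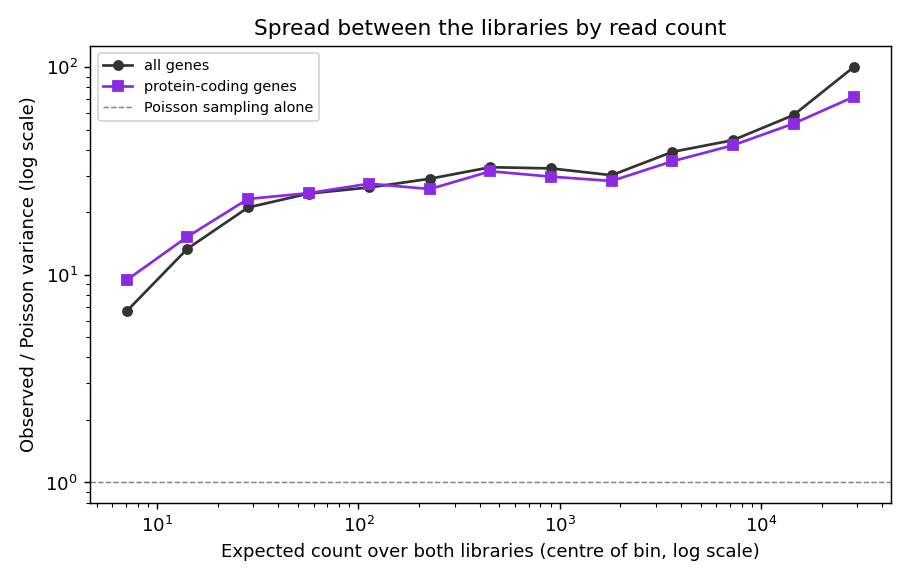
Observed variance of a gene's split between the libraries over the Poisson variance, on log axes, in bins of the gene's expected count over both libraries, for all genes and for protein-coding genes, leaving out bins up to 5 and over 40960 reads. The dashed line is Poisson sampling alone. For all genes the ratio was 26.4 at 80 to 160 reads and 30.2 at 1280 to 2560 reads.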

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

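Outside the gene entries, the entry with numeric identifier 46219 had 83 expected counts in replicate 2 and 0 in replicate 1. It was flagged because a count of 0 allows 3 counts by counting error alone and all other entries of its kind were at 0. Such a split was not rare in these libraries. Of genes with 80 to 160 reads over both libraries, 11.9% rounded to 0 counts in replicate 1. The tables do not name the feature, and no explanation was tested.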

How the results depend on the processing

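Settings for protein-coding genes, 1000 counts, GC bins and rescaled TPM were chosen after seeing the data. Lists with a median of at least 1 TPM in both libraries numbered 18 of 25, 18 to 20 in a single library, 20 with FPKM, 21 with CPM or with TPM rescaled to nuclear protein-coding genes and 23 over members at 10 counts. Detected genes numbered 10418 to 10796 in a single library, 5737 at 5 TPM, 12981 at 0.1 TPM, 13296 at 10 counts, 11407 with FPKM and 12186 with rescaled TPM. The granulocyte-monocyte minus megakaryocyte-erythroid difference stayed negative: -2.17 to -2.15 in a single library, -2.55 with a pseudocount of 0.1, -1.64 with means, -2.70 with CPM and -1.82 over members at 1 TPM. No alternative put other factors in these lists. Pearson r was 0.876 with a pseudocount of 0.1, 0.978 over all genes, 0.975 at 5 TPM and 0.969 over protein-coding genes. The coefficient of variation was 0.59 with no filter, 0.162 at 5 CPM, 0.199 over protein-coding genes and 0.121 at 1000 counts. Genes differing at least 2-fold numbered 3136, 411 and 50 at mean counts of 10, 200 and 1000, and 854 over protein-coding genes. With TPM ratios, whose median over genes was 0.22 on the log2 scale, 1317 were higher in replicate 2 and 472 in replicate 1. Lists outside the central 95% numbered 2 at a mean count of 50, the progenitor factors joining the histones. The length range was 0.17 with effective lengths, 0.21 at a mean count of 200 and 0.23 over protein-coding genes. Nuclear protein-coding genes held 80.99% of expected counts. The same transcript was dominant for 60 of 66 genes by shares of expected counts and for 46 of 54 at 500 counts. The causes of these changes were not tested. Results between the libraries allow no leaving out of a replicate. No paired analysis of conditions was possible because there was 1 group.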

Other observations

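The tests of the snoRNA and short RNA shares, of independent molecules and of a constant variation between mice were chosen after the result was seen, as were the gene families and Terc. 9 of 9 Hoxc genes, 9 of 9 Hoxd genes and 7 of 10 Hoxb genes had 0 counts in both libraries. Among Hox genes, Hoxa9 stood at 10.99 ± 1.01 TPM and Hoxa7 at 3.37 ± 1.24 TPM (SD, n = 2), and they were the 2 that reached 1 TPM in both libraries; with TPM rescaled to nuclear protein-coding genes 6 did, 1 of them, Hoxb4, outside the Hoxa cluster. Of 12 Toll-like receptor genes, Tlr2 at 1.98 ± 0.148 TPM was the one at 1 TPM in both, and with rescaled TPM 4 were: Tlr2, Tlr4, Tlr6 and Tlr7. Of 18 chemokine receptor genes, 4 reached it on either scale: Cxcr4, the receptor that holds progenitors in the marrow, at 20.3 ± 5.74 TPM, Ccr2 at 10.4 ± 0.686 TPM, Cxcr2 at 2.05 ± 0.127 TPM and Cx3cr1 at 1.8 ± 0.226 TPM. Terc, the telomerase RNA, had 163 and 0 counts in replicates 1 and 2 and was the median member of the long noncoding and structural RNA list in replicate 1 alone.

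The spread between the libraries at low counts far exceeded Poisson sampling. If reads were drawn in clumps from fewer molecules, the ratio of observed to Poisson variance would stay level over low and middling counts. The ratio at 1280 to 2560 reads was 1.15 times that at 80 to 160 reads (interval over genes 1.01 to 1.3). Outside these bins the ratio was 6.69 at 5 to 10 reads and 101 at 20480 to 40960. Where all reads of a gene fall in 1 library, the ratio averages the gene's total. The value at 5 to 10 reads is thus limited by the count and decides nothing. A constant relative variation between mice or isolations would make the excess grow with the count, and it grew 1.15-fold (interval 1.02 to 1.32), which argues against a constant variation as the main source at these counts; at higher counts, where the ratio rises, it stays open. Genes with whole counts in both libraries kept a variance ratio of 26.1 at 80 to 640 reads (interval 24.7 to 27.7). This argues against reads divided in fractions between similar genes as the main source. Reads given wholly to 1 of several similar genes would also leave whole counts, so that case stays open. Reads that are not independent molecules may be the source, and a variation between mice or isolations that is larger for low genes stays open and untested.

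The snoRNA share of TPM was 23.99% in replicate 1 and 11.8% in replicate 2. The effective length correction alone would leave the shares of expected counts alike, but their ratio was 0.634 (interval 0.608 to 0.662, counting error widened by the variance ratio). Gm22422 alone would leave the share alike without it, but that ratio was 0.733 (interval 0.697 to 0.772). A lower recovery of all short RNAs in replicate 2 would lower the others as well, but gene models under 200 nt other than snoRNA and scaRNA, nearly all their reads from snRNA, had a ratio of 1.32 (interval 1.28 to 1.35) in shares of expected counts. The variance ratio was 101 at 20480 to 40960 reads and 729 above that. The intervals of these shares, held largely by genes with many reads, may thus be too narrow, and the ratio of 0.733 is less certain than its interval. Without Gm22422 and Gm23245, both of 135 nt and chosen because they fell, the ratio was 0.909 in TPM and 0.893 in expected counts, so these 2 gene models carried most of the difference; what lowered them stays open, and no biological explanation was tested.

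Replicate 2 was higher in long genes. The modelled fragment lengths differed, 215 nt in replicate 1 and 202 nt in replicate 2, but the range of bin medians with TPM ratios was 1.22 times that with CPM ratios (interval 1.12 to 1.48) where this explanation needs a smaller one. Removing the GC trend left a range 1.13 times as large (interval 1.06 to 1.31), which argues against GC content. A difference in library size selection or RNA quality stays open and untested, as does any biological explanation, since both libraries are of 1 group. The ratio rose with GC content: the median log2 ratio of the fifth of protein-coding genes with the highest exceeded that of the lowest by 0.14 (interval 0.11 to 0.16); the bounds set for this value beforehand decide nothing, since it is the trend itself.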
